A study of Homo sapiens with 8 samples.

How the data were processed

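RNA was measured by sequencing in 8 libraries of K562 cells, an established human chronic myeloid leukemia line that can be driven towards megakaryocyte-like or erythroid-like cells. Per the labels' protocols, 4 libraries came from cells given an extract of the stem of a medicinal plant, Caulis Polygoni Multiflori, at 80 µg/mL for 3 days. The other 4 came from cells without the extract and are called control, with no time in culture given for them. RNA was taken with TRIzol and libraries were made with a TruSeq kit, per the labels' protocols. Whether the kit marked strand was not given in the sources used here. Nothing in the labels said that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

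The submitters' processing notes name HISAT2, StringTie and the build GRCh38, with no version or role. The deposited table held 1 expression value per gene and library, with 2 decimals, and the group means made by the authors equalled the means of these values. The unit of the values was not given in the sources used here, so they are called expression values and cannot be read as TPM or FPKM. They were not counts. Low values of genes with 1 annotated transcript lay near whole multiples of the gene's lowest value in 21.9% of 1133 cases, against 21.2% by chance, within a tolerance set by the 2 decimals. Reads per library could therefore not be recovered and the depth is unknown. No interval for counting error is given.

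The authors' deposited table also gave a fold change (a ratio of extract over control), its log2, a p-value and an adjusted p-value per gene. The tool behind them was not given in the sources used here. The table listed 1950 genes, and each one had a deposited p-value of 0.0499 or less and an absolute deposited log2 fold change of 0.5851 or more, which is a change of at least 1.5-fold. So the table holds genes already chosen for a difference between these same libraries. Dividing each deposited adjusted p-value by its p-value gave whole-number ranks (within 0.02) for 100% of 1379 usable genes under a Benjamini-Hochberg family of 60664 genes. The rank of the highest listed p-value was 8138, against 3033 by chance if all 60664 genes could reach a p of 0.05. Genes without reads cannot, and how many of these the family held is unknown, so 3033 is only a rough guide. The step at an adjusted p of 0.05 fell between ranks 5190 and 5210, so most genes past that threshold changed less than 1.5-fold and were not analysed here.

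The main test was limma 3.58.1 in R 4.3.3, with trended and robust empirical Bayes moderation, on log2(value + 1). Genes with a value of at least 1 in at least 4 of the 8 libraries were tested, which left 750 of the 1950. Each log2 change is on the log2(value + 1) scale and understates the change of low genes. Adjusted p is the Benjamini-Hochberg value over these 750 genes, called at 0.05. Since the genes were chosen on the same libraries, neither the number of calls nor any single call is independent evidence of a difference. For that reason the limma p-values were also adjusted over the family of 60664 genes, an alternative added after the data were seen. Taking these p-values as given, it understates the calls, because genes not listed do not enter the ranks. The p-values themselves rest on variances moderated over the chosen genes only and may be too small, so the result is not a sure lower bound.

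There were 26 gene lists and 20 single genes fixed before the data were examined, as were the test, the naming rule and the alternatives, except those added after the data were seen. Lists with at least 2 tested members, 9 of the 26, were tested with camera at an inter-gene correlation of 0.01, as 1 Benjamini-Hochberg family. The background of camera was the other tested genes, which were themselves chosen as changed. camera with an estimated correlation and fry were alternatives. The naming rule took called genes whose groups did not overlap and whose mean level was at or above the median of 3.33. From these came the 12 largest rises and the 12 largest falls, without pseudogenes and unnamed loci. It also took up to 4 tested members of each list, by lowest p, and the 20 single genes, of which 3 were in the table. The rule took 49 genes in all, and the result of 1 list is not reported here. Principal components used all 750 tested genes, in place of the planned 1000 most variable, because fewer were tested.

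The limma step was tested on simulated data, with 200 changed genes among 750 in the comparison of extract with control. It recovered 23.5% of genes changed 1.25-fold, 69.5% of those changed 1.5-fold and 86.5% of those changed 2-fold. False calls made up 4.1%, 4.1% and 3.9% of all calls. In camera, 5 of 200 unchanged simulated lists had p under 0.05. The simulated genes varied independently and were not chosen for a difference. These rates therefore need not hold for the tested genes, which were so chosen. Permutations, binomial intervals and figures used Python 3.11.15 with scipy 1.17.1, pandas 2.3.3 and numpy 2.4.6. Gene coordinates, exon lengths and transcript numbers came from GENCODE 29 on GRCh38, which held 1866 of the 1950 gene identifiers. Of these 49 genes, 27 overlap another annotated gene, 15 of them on the same strand, and reads of overlapping genes may not be told apart in these values. The alternatives were a replicate block, leaving out each library, median centring, quantile normalization, other filters, limma without trend, other pseudocounts and, added after the data were seen, the authors' adjusted p.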

Results

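K562 leukemia cells grown for 3 days with the plant extract at 80 µg/mL were compared with cells without it, 4 libraries against 4. The labels give no time in culture for the control cells, so a difference in that time cannot be separated from the extract. The series title names the question, whether the extract promotes the formation of megakaryocytes and platelets through PI3K/AKT and MEK/ERK signaling. The deposited table lists 1950 genes chosen by the authors' own test, 850 higher and 1100 lower with the extract. An adjusted p under 0.05 in the authors' deposited table was given for 896 of these, 356 higher and 540 lower. The other 1054 were mostly low, with a median expression value of 0.2 against 2.05 for the 896. The listed values of a library summed to between 13114 and 14134, which is no measure of depth because the list is partial. Everything below concerns the listed genes, and a gene not in the list was not analysed here.

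Cells given the extract had more RNA of the transcription factor MYC, the hemoglobin zeta chain HBZ, the heat shock protein HSPA1B and the kinase PIM1, and less of ACSM3, GMFG and TMEM160. MYC (chromosome 8, 127735434 to 127741434, GRCh38) rose from 141 ± 2.49 to 295 ± 7.33 (SD, n = 4 each), a 2.08-fold difference of means. HBZ (chromosome 16, 152687 to 154503), a globin of early erythroid cells, was the most abundant gene of the list and rose from 2876 ± 47.2 to 5097 ± 149. HSPA1B rose from 95.03 ± 3.34 to 193 ± 3.82, although its copy HSPA1A is nearly identical and reads of the 2 genes may be shared. ACSM3 (chromosome 16, 20610243 to 20797581), a mitochondrial acyl-CoA synthetase gene, fell from 134 ± 5.26 to 51.0 ± 1.88, a 2.62-fold difference. TMEM160, a short gene, had the largest fall by the naming rule, from 33.8 ± 11.02 to 7.41 ± 1.79. Its control values were uneven, from 18.99 in control 5 to 44.17 in control 3. In each of these genes all 4 extract libraries lay on one side of all 4 control libraries, as the naming rule required.

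In limma 621 of the 750 tested genes had an adjusted p under 0.05, of which 201 were higher and 420 lower with the extract. Of these, 363 differed by at least 1.5-fold, 93 higher and 270 lower. Adjusted over the authors' family of 60664 genes, 167 calls were left, 45 higher and 122 lower. The split also depended on scaling, but centring on genes chosen as changed, most of them lower, brings it near balance by construction. Which scaling is nearer the truth cannot be told from these genes. With the libraries centred on the median of the tested genes, which differed by −0.27 (log2) between extract and control, 228 genes were higher and 241 lower. Relative to this shift, the median log2 change was 1.06 for the tested JAK/STAT genes described below, −0.36 for the MEK/ERK outputs and −0.30 for the megakaryocyte and platelet genes. The groups did not overlap for 508 of the 750 tested genes, against 2.9% of genes by chance, but the genes were chosen for their difference.

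IL10RA, ESPN, FN1 and SGK1 were among the other genes with the largest rises. IL10RA, a chain of the interleukin-10 receptor, rose from 5.28 ± 0.32 to 12.98 ± 0.941. The actin-bundling gene ESPN rose from 11.4 ± 1.37 to 26.5 ± 0.554, the fibronectin gene FN1 from 4.36 ± 1.06 to 9.46 ± 0.395, and the kinase gene SGK1 from 3.87 ± 0.567 to 7.98 ± 0.687. MUC4, P2RY11 and NPR2 rose by 0.83 to 0.84 on the log2 scale. Among the largest falls, GMFG, which codes for an actin regulator of blood cells, went from 48.4 ± 4.69 to 17.9 ± 1.99. TNNI3, the cardiac troponin I gene, went from 56.1 ± 5.58 to 25.6 ± 2.13. C4orf48, INAFM1, CRYBA4, RANBP3-DT, SLC25A48, EVA1B, C9orf135 and CFAP161 fell by 1.86, 1.75, 1.58, 1.46, 1.45, 1.30, 1.29 and 1.11 on the log2 scale, in that order. The calls of C4orf48, INAFM1, RANBP3-DT and EVA1B were lost over the family of 60664 genes, with adjusted p = 0.867, 0.116, 0.0735 and 0.0517 in limma.

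The few genes in the table from the fixed list of cytokine signaling through JAK and STAT were higher with the extract. Of the 20 genes of the list of JAK/STAT receptors and targets 4 were in the table, and all 4 rose. These were CISH, SOCS1 and SOCS3, which code for feedback inhibitors of the pathway, and PIM1, a target kinase. CISH (chromosome 3, 50606490 to 50611831) rose from 60.2 ± 1.34 to 115 ± 1.21 and PIM1 (chromosome 6, 37170203 to 37175426) from 211 ± 8.39 to 400 ± 12.9, with n = 4 in each group. SOCS3 rose from 6.09 ± 0.478 to 9.08 ± 0.0902 and SOCS1 from 2.05 ± 0.598 to 3.80 ± 0.214. The 4 members also passed when adjusted over the list alone. Here and in the lists below such a pass adds no support, because the listed genes were chosen for their difference. This was the list that stood apart from the other tested genes in camera (adjusted p = 0.00293, up), with adjusted p = 0.113 with an estimated correlation. Most of those other genes fell (420 lower and 201 higher among all calls), so a few rising genes stand apart from them easily. The call of SOCS1 was lost over the family of 60664 genes (limma adjusted p = 0.252). The other genes of the list were not in the table, among them JAK2 and STAT5A and the further targets SOCS2 and PIM2. A rise of the targets as a whole is therefore not shown.

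Most tested genes of the list of MEK/ERK outputs and immediate-early genes were lower with the extract. Of its 30 genes, 9 were in the table and 6 were tested, and 1 rose and 5 fell, over all tested genes and adjusted over the list alone. MYC was the gene that rose. EGR1 (chromosome 5, 138465490 to 138469315), an early growth response factor, fell from 37.1 ± 1.95 to 22.0 ± 0.793. The cyclin D1 gene CCND1 (chromosome 11, 69641087 to 69654474) fell from 28.3 ± 0.629 to 17.2 ± 0.817, ATF3 from 8.17 ± 0.294 to 4.04 ± 0.878 and IER3 from 12.1 ± 0.815 to 7.92 ± 0.871. SPRY1, an inhibitor of the pathway, went from 1.69 ± 0.375 to 1.12 ± 0.31 at a limma adjusted p of 0.0488. Its call held in only 2 of the 8 fits that left out 1 library. It was lost without extract 1, 2 or 4 or control 2, 4 or 5, with adjusted p between 0.0263 and 0.121 over the 8 fits. Of FOSB, PHLDA1 and EPHA4, which were too low to test, the authors' deposited table gave log2 fold changes of −1.57, 0.67 and −2.34. The list as a group did not stand apart from the other tested genes in camera (adjusted p = 0.514, and adjusted p = 0.556 with an estimated correlation). The calls of EGR1 and SPRY1 were lost with quantile normalization (limma adjusted p = 0.0561 and 0.173), that of SPRY1 with median centring (adjusted p = 0.61), and those of IER3 and SPRY1 over the family of 60664 genes (adjusted p = 0.0617 and 1). None of the 30 genes that code for components of the MEK/ERK cascade were in the table (0 listed).

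Of the 30 PI3K/AKT components 2 were in the table, and they moved in opposite directions. IRS1 (chromosome 2, 226731317 to 226799759), an adaptor that recruits PI3K to receptors, rose from 0.55 ± 0.102 to 1.82 ± 0.363. INPP5D (chromosome 2, 233059967 to 233207903), which codes for the lipid phosphatase SHIP1, fell from 4.32 ± 0.66 to 2.19 ± 0.383. Both passed in limma, over all tested genes and adjusted over the list alone. The list did not pass in camera (adjusted p = 0.594, and adjusted p = 0.625 with an estimated correlation). The call of INPP5D was lost over the family of 60664 genes (limma adjusted p = 0.117).

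Of 20 targets of FOXO factors, which AKT restrains, 7 were in the table, 2 higher and 5 lower, and 3 were tested. TXNIP rose from 102 ± 1.77 to 162 ± 2.62, and PDK4, a kinase that inhibits the pyruvate dehydrogenase complex, fell from 5.07 ± 0.469 to 1.86 ± 0.185. The cyclin G2 gene CCNG2 fell from 1.86 ± 0.258 to 1.26 ± 0.328. Thus 1 of the 3 tested genes rose and 2 fell, with all 3 past the threshold adjusted over the list alone. Of the genes too low to test, IRS2, PIK3IP1 and FBXO32 had log2 fold changes of −0.76, −0.996 and −0.86 and INSR 0.85 in the authors' deposited table. The median and mean log2 change were −0.35 and −0.26, while camera gave the direction up relative to the other tested genes (adjusted p = 0.89, and adjusted p = 0.916 with an estimated correlation). The call of CCNG2 was lost without extract 2 or 3 or control 2, 3 or 5 (limma adjusted p between 0.0249 and 0.0864 over the 8 fits). It was also lost with median centring (adjusted p = 0.564), with quantile normalization (adjusted p = 0.203), without a filter (adjusted p = 0.0567) and over the family of 60664 genes (adjusted p = 1).

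**Figure D1:**
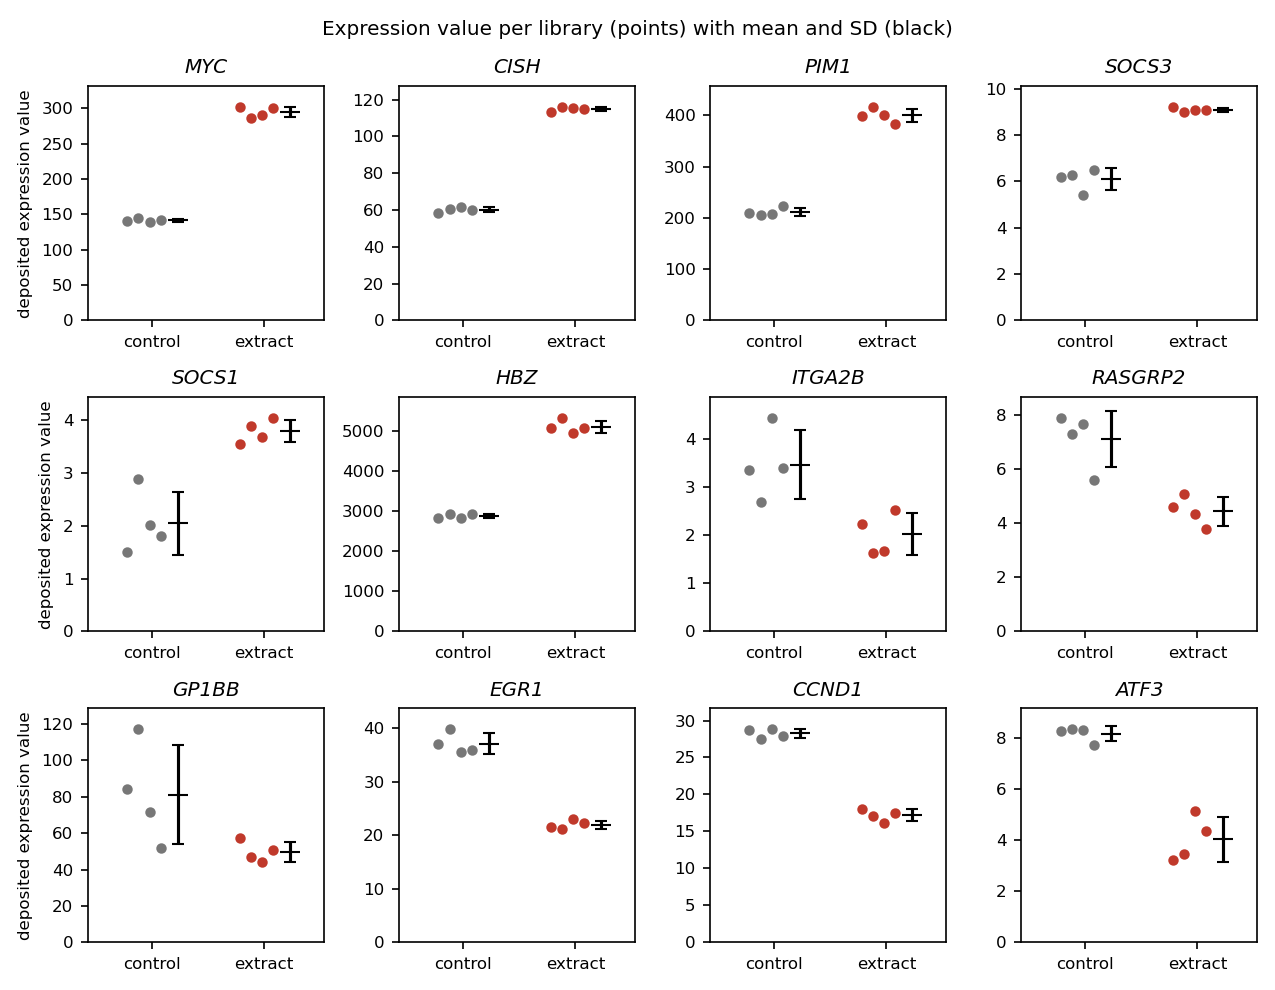
Deposited expression value (vertical axis, linear from 0, unit not given) of 12 named genes in the 4 control and 4 extract libraries. Points are libraries and black marks are the mean with its SD; MYC lies between 138 and 144 in the controls and between 286 and 301 with the extract, while the groups overlap for GP1BB.

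Genes of megakaryocytes and platelets that could be tested were lower with the extract. Of 40 genes in the list, 7 were in the table, 3 higher and 4 lower, and the 3 that could be tested all fell, also adjusted over the list alone. ITGA2B (chromosome 17, 44372180 to 44389505), which codes for the integrin chain CD41, fell from 3.48 ± 0.718 to 2.02 ± 0.438. RASGRP2 (chromosome 11, 64726911 to 64745456), which activates integrins in platelets, fell from 7.12 ± 1.05 to 4.45 ± 0.53. GP1BB (chromosome 22, 19722945 to 19724771), a chain of the von Willebrand factor receptor, fell from 81.2 ± 27.3 to 49.8 ± 5.63, and its annotation overlaps that of SEPT5. THBS1, too low for the test, had expression values of 0.57 ± 0.208 and 1.12 ± 0.451 and a log2 fold change of 0.94 in the authors' deposited table. Camera did not separate the list from the other tested genes (adjusted p = 0.514, and adjusted p = 0.556 with an estimated correlation). The calls of ITGA2B, RASGRP2 and GP1BB were lost with median centring (limma adjusted p = 0.105, 0.0655 and 0.171) and over the family of 60664 genes (adjusted p = 0.786, 0.286 and 1), and that of ITGA2B with quantile normalization (adjusted p = 0.0976). GP1BB also lost its call without extract 2, extract 3 or control 2 (limma adjusted p = 0.0568, 0.0614 and 0.0583), and its log2 change was 0.02 with quantile normalization. Both scalings used genes chosen as changed, so the losses under them do not tell a scaling shift from a real fall.

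The genes of the fixed erythroid list that were in the table were higher with the extract. Of 40 genes in the list 3 were listed, all 3 higher in the authors' deposited table. HBZ was tested and rose, with no difference (log2 0.00) after quantile normalization, which gives the highest gene of every library 1 value. SLC4A1, the anion exchanger of red cells, had values of 0.628 ± 0.18 and 1.04 ± 0.156, and TMCC2 had 0.44 ± 0.102 and 1.03 ± 0.204, below the filter. In the authors' deposited table their log2 fold changes were 0.64 and 1.29. Of 20 transcription factors of both lineages 2 were in the table. ZFPM1 (chromosome 16, 88453317 to 88537016), the partner of GATA1 known as FOG1, rose from 15.3 ± 0.65 to 25.9 ± 1.56. SPI1 (chromosome 11, 47354860 to 47378576), which codes for the myeloid factor PU.1, fell from 10.0 ± 0.221 to 6.14 ± 0.995. Both also passed adjusted over the list alone, and the list did not pass in camera (adjusted p = 0.594, and adjusted p = 0.625 with an estimated correlation). The call of SPI1 was lost over the family of 60664 genes (limma adjusted p = 0.0871). Of the 20 single genes fixed before the data were examined 17 were not in the table and were not analysed here, among them ITGB3, GP1BA, GATA1, FLI1, RUNX1, NFE2, HBG1, FOS, DUSP6 and AKT1.

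**Figure D2:**
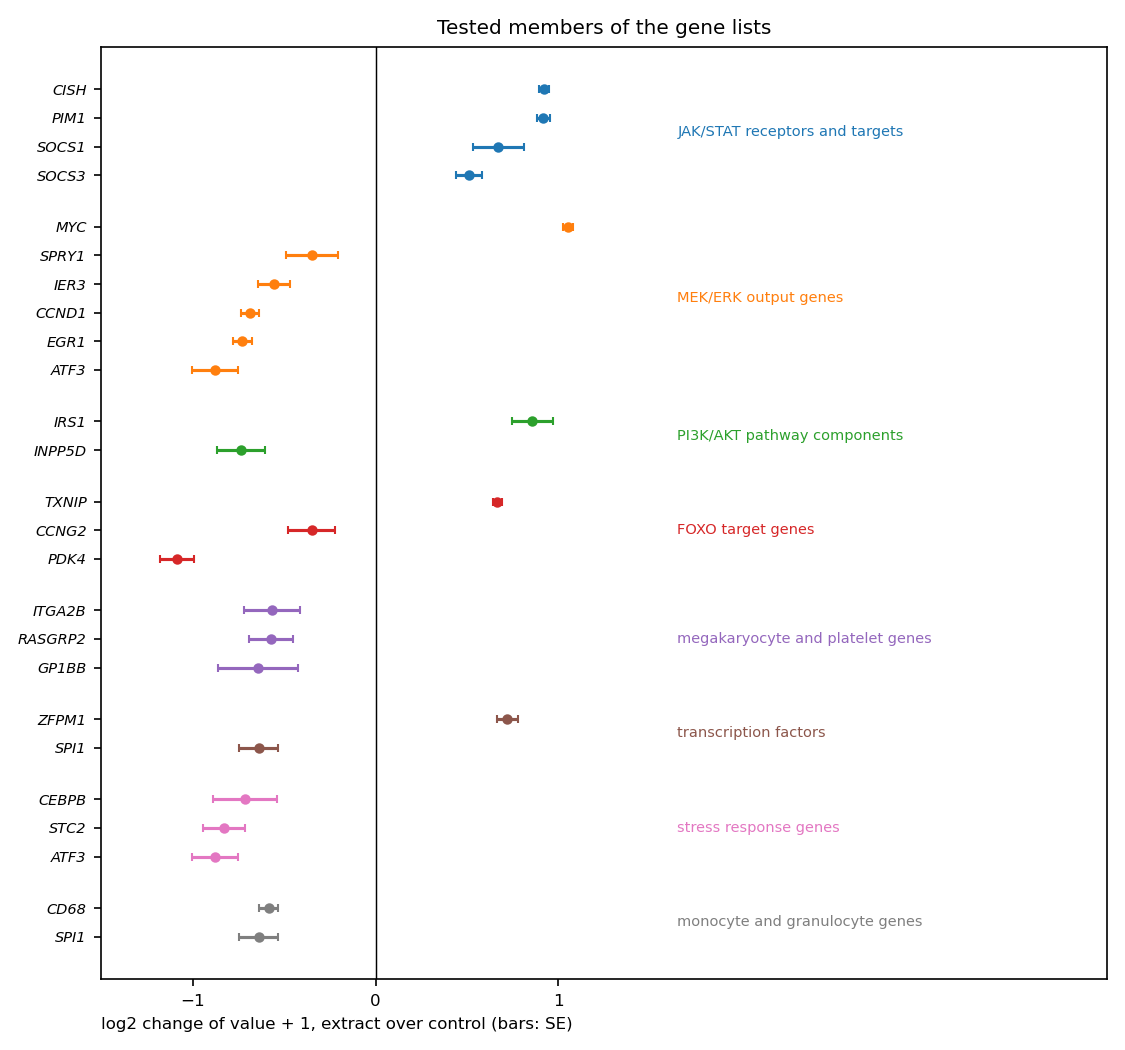
Log2 change of value + 1 (horizontal axis, extract over control) for the tested members of 8 gene lists with at least 2 tested members each. Points are limma estimates from 4 libraries a group and bars their SE; all 4 JAK/STAT genes lie to the right of 0 and all 3 megakaryocyte and platelet genes to the left.

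Stress and metabolic genes in the table were few. In the list of the integrated stress response and the unfolded protein response 3 of 25 genes were listed and all 3 fell. These were ATF3, the hormone gene STC2 (8.81 ± 0.861 to 4.54 ± 0.723) and the transcription factor gene CEBPB (9.38 ± 2.61 to 5.21 ± 0.643). They also passed adjusted over the list alone, but the list did not pass in camera (adjusted p = 0.402, and adjusted p = 0.556 with an estimated correlation). The call of CEBPB was lost with median centring (limma adjusted p = 0.0543) and over the family of 60664 genes (adjusted p = 0.523). Of 15 heat shock genes only HSPA1B was listed, and of 23 cholesterol synthesis genes only MSMO1, which rose from 28.97 ± 1.49 to 48.2 ± 1.98. The glucose transporter gene SLC2A3 fell from 43.3 ± 1.85 to 21.3 ± 1.04, and CA9 was the other of 25 glycolysis and hypoxia genes listed, at values under 1. BBC3, a BH3-only death gene in the lists of p53 targets and of the BCL2 family, fell from 13.2 ± 1.55 to 6.29 ± 1.04. SLC7A11, the cystine transporter and the 1 listed gene of 25 NRF2 targets, fell from 4.61 ± 0.414 to 2.80 ± 0.17, a call lost over the family of 60664 genes (limma adjusted p = 0.0625).

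The few tested genes of the fixed lists for other blood cells were lower with the extract. Of 20 monocyte and granulocyte genes 2 were listed, SPI1 and CD68, which fell from 22.3 ± 0.737 to 14.6 ± 0.75. Both passed adjusted over the list alone, and camera gave adjusted p = 0.402 for the list (adjusted p = 0.556 with an estimated correlation). CD3D, a T-cell gene, fell from 42.3 ± 1.70 to 19.7 ± 2.10. MLLT3, a regulator of blood stem cells and 1 of 2 listed stem and progenitor genes, fell from 37.8 ± 3.72 to 21.8 ± 2.46, a call lost with quantile normalization (limma adjusted p = 0.155). The cytoskeleton, interferon and epithelial and fibroblast lists each had 1 listed gene, WAS, OAS2 and COL1A1, all under the filter and lower in the authors' deposited table. No gene was listed (0) from the lists of S-phase, mitosis, AHR target, mitochondrially encoded or ribosomal protein genes.

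The libraries separated by group. On the 750 tested genes, Pearson correlations of log2 values lay between 0.938 and 0.962 within groups and between 0.819 and 0.875 across groups, and no pair was identical. The first principal component held 62.6% of the variance and parted extract from control, as it must for genes chosen for that difference. The second held 7.97% and set control 5 (−8.97) apart from the other libraries, which lay between −2.18 and 4.13.

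The deposited fold change was not the ratio of the deposited group means. Among 1539 genes with both group means above 0, the ratio of means was under 1.5-fold for 164 genes and opposite in sign to the fold change in the authors' deposited table for 12. CD3D, a gene of the T-cell receptor complex, had a log2 fold change of −0.66 in the authors' deposited table, against −1.10 for the ratio of means. For ESPN, among the largest rises above, the values were 0.80 and 1.22. For ACSM3 they were −1.24 and −1.39, and for MYC both were 1.06.

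**Figure D3:**
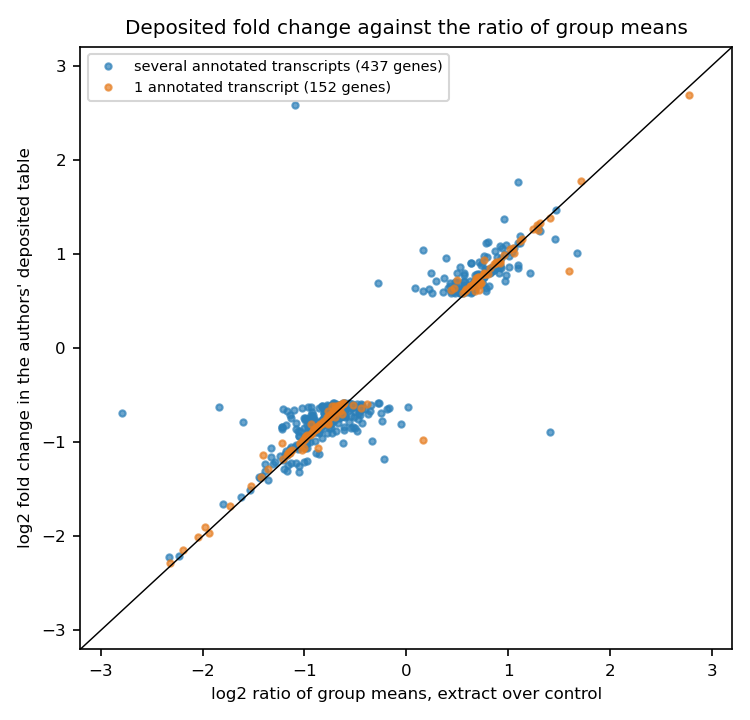
Log2 fold change in the authors' deposited table (vertical axis) against the log2 ratio of the deposited group means (horizontal axis), extract over control, for 589 genes with both means at least 1 and a known number of transcripts. The line marks equal values; the 152 genes with 1 annotated transcript lie closer to it than the 437 with several.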

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

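Of 106 groups of 4 libraries, from the named genes and from the library totals and components, 7 held a library far from the other 3, where chance alone gives about 5.3. No explanation is offered for them. FN1 was lowest in extract 1 (8.87, others 9.56 to 9.70), and CFAP161 was highest in control 5 (14.88, others 11.01 to 11.55). ATF3 was lowest in control 5 (7.73, others 8.29 to 8.34), and BBC3 was highest in control 3 (15.49, others 12.35 to 12.44). MSMO1 was highest in extract 3 (51.14, others 46.98 to 47.38). SLC2A3 was highest in extract 1 (22.85, others 20.64 to 20.86), and CD3D was highest in extract 2 (22.87, with 18.5 the lowest of the others). In each of these 7 genes the far library stayed on its own group's side of the other group.

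A further pattern was noticed after the data were seen, among genes that were lower with the extract. C4orf48 had an expression value of 81.91 in control 3 and 12.08 in control 5, and GP1BB 116.97 and 52.05. The gap went the same way for TMEM160 (44.17 and 18.99), INAFM1 (17.13 and 7) and CEBPB (12.94 and 6.7). Other falling genes, such as CFAP161 (11.52 and 14.88) and STC2 (8.74 and 10.04), were higher in control 5. The third of tested genes highest in control 3 over control 5 had a median GC content 2.05 percentage points above that of the other tested genes (95% bootstrap interval −0.442 to 4.49, permutation p = 0.081, two-sided), below the 5 points that GC bias would have needed. Its median exon length was 0.759 times that of the other genes (interval 0.66 to 0.918, permutation p = 0.0017, two-sided), as a length bias would need. Across the tested genes the Spearman correlation of the difference with exon length was only −0.082, and it was −0.08 for extract 3 against extract 4. With GC content the correlation was 0.111 for control 3 against control 5. Over pairs of controls it was 0.085 to 0.118 in those with control 5 and −0.03 to 0.021 in the others. It was 0.097 for extract 1 against extract 3. The limit of 5 points does not exclude a smaller GC bias. So any length bias was weak and not particular to these 2 libraries. Any GC bias was weak as well, and how much of the pattern either accounts for stays open. Genes are not independent replicates, and a difference between the cultures stays open and untested. Without control 3 the log2 change of C4orf48 was −1.42 and without control 5 it was −2.31, with limma adjusted p = 0.0143 and 0.00182.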

How the results depend on the processing

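Chosen after the data were seen were the authors' adjusted p, the adjustment over 60664 genes and the 6 libraries without a block. The count of 621 called genes lay between 538 and 584 with 1 library left out, and was 469 with median centring, 473 with quantile normalization, 618 without trend, 597 and 617 with pseudocounts of 0.1 and 0.5, and 874 of 1947 genes without a filter. By the authors' adjusted p it was 608, with 530 shared. With values of at least 5 it was 253, and 198 at 1.5-fold, because 277 genes were tested. Over 60664 genes it was 167, and 146 at 1.5-fold, by the construction of the adjustment. The replicate block over numbers 2, 3 and 4 gave 515 calls, against 527 for the same 6 libraries without it. Same-numbered libraries deviated together by r = 0.075, 0.075 and 0.149, against −0.124 to 0.136 for libraries of unlike number. Control 3 and control 4 went best with the extract library of their own number, and control 2 with extract 1 (0.136). Whether the numbers pair the libraries stays open, and they are not taken to do so.

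Of the gene lists, 1 passed in camera and 2 without a filter, where erythroid genes gave adjusted p = 0.0206 because more members entered. With an estimated correlation 0 passed (JAK/STAT adjusted p = 0.113; with the preset correlation its range was 0.00079 to 0.011 over 17 alternatives). With fry, which compares a list with no other genes, 7 passed, among them megakaryocyte and platelet genes (down, adjusted p = 0.00137) and MEK/ERK outputs (down, 8.02e-05), and JAK/STAT (up, 6.37e-07). The listed genes were chosen for their difference in these same libraries, so passing in fry is no added evidence. Of 49 named genes 41 kept direction and call in all alternatives but the adjustment over 60664 genes, under which 13 lost the call. GP1BB reversed with quantile normalization (log2 0.0187), and the cause was not tested. HBZ had a log2 change of 0 there, since the highest gene of every library is given 1 value. Count-based size factors, a negative binomial test, upper-quartile scaling, voom and removal of the 10 most counted genes were not run, because the values were not counts. Depth is unknown, so it is open which low genes it limits.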

Other observations

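The genes in this part were chosen after their values were seen, and the test of rounding and low values was set after its result. No fixed list or enrichment test stands behind the gene groups given here, and 420 of the 621 called genes fell, so a few related genes falling together is common among these genes. The inhibitors of DNA binding ID1, ID2 and ID3, which block helix-loop-helix transcription factors, all fell, from 61.3 ± 7.95 to 34.0 ± 2.80, from 6.72 ± 0.439 to 2.75 ± 0.555 and from 15.7 ± 1.62 to 9.44 ± 1.47 (SD, n = 4 each). The direction held under both scalings, but ID1 was not called with quantile normalization (limma adjusted p = 0.0855) nor ID3 over the family of 60664 genes (adjusted p = 0.0858). The selenoprotein genes SELENOW, SELENOH and SELENOP fell by 0.95, 0.74 and 0.64 on the log2 scale, with SELENOW not called under quantile normalization (limma adjusted p = 0.0598). S100A4, S100A16, S100P and S100A10, which code for small calcium-binding proteins, fell by 0.94, 0.84, 0.74 and 0.72 on the log2 scale. The call of S100A10 was lost under both scalings (limma adjusted p = 0.094 and 0.0777) and over the family of 60664 genes (adjusted p = 1). TMSB4X, which codes for the actin-binding thymosin beta 4, fell from 1122 ± 33.2 to 593 ± 6.12. Its log2 change was 0 under quantile normalization (limma adjusted p = 1), which gives a gene of the same rank in every library 1 value.

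TXNIP and ARRDC4, arrestin genes that respond to glucose metabolites, rose by 0.67 and 0.63 on the log2 scale. The glucose transporter genes SLC2A3, SLC2A14 and SLC2A4 fell by 0.99, 0.87 and 0.56 on the log2 scale. SLC2A3 and SLC2A14 are close copies, so their values may not be independent, and SLC2A3 fell by 0.37 on the log2 scale with quantile normalization. Both receptors for thrombin that were tested fell, F2R from 8.67 ± 0.883 to 5.02 ± 0.421 and F2RL3 from 14.9 ± 0.719 to 8.79 ± 0.414. Among called genes with a symbol, IL6 had the largest rise after the pseudogene RPL22P1, from 0.615 ± 0.194 to 3.81 ± 0.515, a log2 change of 1.58 (limma adjusted p = 2.13e-05), higher in 4 of 4 extract libraries. IL1R1 also rose, while IL16, IL18 and IL23A fell. These directions held under median centring and quantile normalization. The calls of SLC2A4, IL1R1, IL18 and IL23A were lost over the family of 60664 genes (limma adjusted p = 0.146, 0.173, 0.0721 and 0.357).

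Some loci were listed at 0 in every library of 1 group. ENSG00000285245 (chromosome 9, 133098121 to 133163914), which overlaps RALGDS and GBGT1 on the same strand, was at 2.75, 1.78, 1.2 and 1.4 in controls 2 to 5 and listed at 0 in all 4 extract libraries. ENSG00000288634, without a place in the annotation used, was listed at 0 in all 4 controls and at 52.01, 40.06, 81.52 and 18.57 in extract 1 to 4. MLLT10P2, a processed pseudogene, was at 4.09, 4.15, 3.25 and 3.6 in the controls and listed at 0 with the extract. A value of 0 in such a file can be a failed estimate. Other genes were carried by 1 library. PLAU was at 16.89 in extract 3 and between 0.74 and 1.05 in the other extract libraries, with a log2 ratio of means of 1.41 and a log2 fold change of −0.89 in the authors' deposited table.

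The departure of the deposited fold change from the ratio of means was weighed against 2 explanations. Rounding and low values were argued against, since 13 of 207 genes with both means at least 5 departed by more than 1.2-fold from the median departure (log2 0.03). The values follow transcript lengths if they are length-normalized, so a change in the mix of a gene's transcripts could move them and leave a fold change made from reads alone. Measured around the median departure, genes with 1 annotated transcript had a median absolute departure 0.111 times that of genes with several (152 and 437 genes, permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). This is consistent with that explanation, as a hypothesis. Whether the mix of transcripts changed in the cells or only in its estimate stays open, and no biological explanation was tested.

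Several of the largest falls were in short genes, so a bias against short or GC-rich genes in the extract libraries was weighed. Length as the whole cause of the falls was argued against by the third of genes with the greatest exon length. Of these, 65.3% were lower with the extract (158 of 242, exact 95% interval 58.9% to 71.3%). Under 30% had been set beforehand as the share that such a bias would leave. GC content as the whole cause was argued against in the same way, by 71.1% of the third with the lowest GC content (172 of 242, exact 95% interval 64.9% to 76.7%). The pattern itself was weak, with a median exon length of 2628 in 483 lower genes and 2825 in 242 higher genes (permutation p = 0.364, two-sided). Median GC content was 52.2% in the lower genes and 54.2% in the higher genes (permutation p = 0.0894, two-sided), opposite in direction to a bias against GC-rich genes. Genes lower with the extract made up 64.9% of the third with the highest GC content, against the 71.1% above. A smaller part of a length bias, and an effect of the extract on short transcripts, stay open.

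Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many changed genes as the real split (621), namely that split itself, and the highest of the others gave 5. Because the genes were chosen for the real split, this count was fixed in advance and does not say whether chance can be excluded.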
